A study of Arabidopsis thaliana with 12 samples.

How the data were processed

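Nuclei of the root cortex were released by chopping roots of 5-day-old plants and sorted by fluorescence of the reporter and by DNA content, per the labels' protocols. RNA was extracted from about 200000 nuclei per class. Between 45 and 100 ng of RNA, with bacterial poly-A control transcripts added, went through 2 rounds of amplification before hybridisation to Affymetrix ATH1 arrays, per the labels' protocols and the series' design text. Such amplification starts from the 3' end and shortens transcripts at the 5' end, which is why the 3' minus 5' differences of control genes were compared between classes. The deposited values are log2 probe set signals made by RMA, which corrects the background, makes the distributions of the arrays alike and sums up the probes of a set, per the submitters' processing notes; the version of RMA and its settings are not given in the sources used here. The log2 scale was read from the values, whose medians lay between 5.22 and 5.36 on the 12 arrays. Because the distributions were made alike, a change of the total RNA per nucleus with DNA content cannot be seen in these values. No scanner files were used, and no detection call goes with the signals. The table held no columns other than those of the 12 samples.

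Arrays were grouped by the DNA content in their titles, 4 classes of 3. The 64 control probe sets were left out of the tests. A linear model over all 12 arrays, without a block, was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes), so that all classes shared 1 estimate of the spread per probe set. The classes were not equally spread. Arrays of 2C correlated with each other at 0.9374 to 0.9735, and those of 16C at 0.9823 to 0.9963. The shared estimate can thus be too small for 2C, and adjusted p-values of contrasts with 2C can be too low. Contrasts were the 3 neighbouring steps, 16C against 2C, the slope per doubling, and the last step minus the first; a moderated F test covered the 3 neighbouring steps. P-values were adjusted by Benjamini-Hochberg over all 22746 probe sets, with a threshold of 0.05. Errors given with changes are the moderated standard errors, and errors given with class means are SDs of 3 arrays. The p-values measure the spread between arrays, which the labels call biological replicates.

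Genes were named through the platform's annotation table, updated by Entrez gene ID to the TAIR10.1 gene table, which 13436 of the 13513 single-gene probe sets matched. A probe set that the table does not list is unnamed here. The table covers genes with established symbols far less than genes with locus codes, so the lists were tested on few members: of 370 listed genes, 65 had a single-gene probe set. For the lists, 16 pathway and 7 marker lists were fixed in advance, with the genes of the plastid and mitochondrial chromosomes as a further list, 24 in all. The probe set with the highest mean stood for a gene, which left 13355 genes. The 10 lists with at least 3 measured genes were tested with limma's camera with a preset correlation of 0.01, with camera with an estimated correlation, and with fry. A list of cytosolic ribosomal proteins was planned by gene description, a column that the tables used here lack, and was not run.

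Named genes were chosen by a rule fixed before the data were examined. For each comparison of 2 classes and for the slope, these were the 10 largest rises and 10 largest falls among called single-gene probe sets whose 3 arrays lay apart between the classes, and all of them where fewer passed. For the slope the arrays of 2C and 16C had to lie apart. For each list, up to 4 called members with the smallest p on the slope and up to 2 more on a neighbouring step were named, or the member with the smallest p where 0 passed, together with 10 genes of the endocycle, mitosis, reporter and neighbouring tissues. RNA quality was compared by the 3' minus 5' log2 difference of GAPDH, with actin as the alternative, by the organelle transcripts and by both sets of spikes, each with an exact permutation test over 369600 assignments of the arrays to classes.

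The alternatives fixed beforehand were the replicate number as a fixed or random block, an intensity trend with robust variances, array weights, leaving out the dimmest 40% of probe sets or those of shared type or without a single gene, cyclic loess, scaling to reference genes, fitting only the arrays compared, a 2-fold minimum and leaving out each array in turn. For lists these were joined by both other set tests and by averaging all probe sets of a gene. Chosen after seeing the data were the poly-A spikes as a covariate, the actin 3' minus 5' difference as a covariate, and averaging 16C replicates 1 and 2. The last was added because these 2 arrays were closer than any other pair of one class; they were kept apart in the main results, since the labels call them separate samples and array noise alone was not measured.

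The fit was tested on simulated data with the real mean and spread of each of the 22746 probe sets, of which 200 were changed. For 8C against 4C it recovered 71 of 100 probe sets changed 2-fold and 94 of 100 changed 4-fold, with 9 false calls. For 4C against 2C it recovered 70 and 93, for 16C against 8C 63 and 92, and for the slope 58 and 92. A spread per probe set holds no difference in spread between classes, so the recovery does not test the fit on that. The real count for 4C against 2C ran from 38 to 438 on leaving out single arrays, which the recovery does not reflect. In 20 simulated data sets of 13355 genes, camera called the shifted list in 20 and 2 of 200 unshifted lists; these simulations hold no correlation between genes. Plots were made with matplotlib 3.10.9 in Python 3.11.15.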

Results

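Nuclei were taken from the roots of 5-day-old Arabidopsis thaliana plants of the Col-0 ecotype. The plants carried a yellow fluorescent protein fused to histone H2B under the promoter of CO2, a gene of the root cortex, which is the ground tissue between epidermis and endodermis. Fluorescent nuclei were sorted by DNA content into 2C, 4C, 8C and 16C classes, where 2C is the content of a diploid nucleus before replication and each further class is a doubling. In the endocycle a nucleus copies its DNA without dividing, so 8C and 16C nuclei have passed through it, whereas a 4C nucleus can also be one that waits to divide. Nuclear RNA of each class was hybridised to ATH1 arrays, with 3 arrays per class and 12 in all. The labels call the arrays of a class biological replicates, without saying which plants or sorts they came from. After leaving out 64 control probe sets, 22746 probe sets were compared, and the number of arrays limits the precision of every value below. The probe table used here named 1 gene for 13513 of them, several genes for 503 and none for 8730. It held 14.6% of the protein-coding genes that have a symbol of their own and 63.1% of those known only by a locus code, so the gene groups below are seen through few of their members.

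The first principal component held 50.3% of the variance, and the 2C and 4C arrays lay on one side of it, between -89.6 and -6.99, and the 8C and 16C arrays on the other, between 27.4 and 61.0. The 16C arrays lay between the 4C and the 8C arrays. Control probe sets moved with the classes as well. The signal at the 3' end of actin exceeded that at its 5' end by 4.55 ± 0.16 (log2, SD, n = 3) in 2C, 3.90 ± 0.11 in 4C, 3.42 ± 0.12 in 8C and 3.80 ± 0.17 in 16C (exact permutation test over all 369600 assignments of the arrays, two-sided by construction, p = 0.00026, adjusted p = 0.0013 over 5 measures). The same difference for GAPDH was 4.85 ± 0.38, 5.2 ± 0.32, 5.05 ± 0.17 and 5.58 ± 0.09 in that order (exact permutation p = 0.0486, adjusted p = 0.0608), and this p lay between 0.0503 and 0.13 without any one array other than 2C replicate 1 (0.0131) and 16C replicate 2 (0.046). The bacterial poly-A transcripts added to each RNA sample averaged 10.9 ± 0.52 in 2C, 10.5 ± 0.58 in 4C, 9.0 ± 1.08 in 8C and 8.94 ± 0.40 in 16C (exact permutation p = 0.0221, adjusted p = 0.0368). The hybridisation spikes also differed, with means of 10.0, 10.4, 9.93 and 10.2 (exact permutation p = 0.000519, adjusted p = 0.0013), and transcripts of the plastid and mitochondrial genomes did not pass this test (exact permutation p = 0.182). The arrays of 16C replicates 1 and 2 correlated at r = 0.996 across probe sets, which are not independent replicates. Any other pair of one class correlated at most at 0.983. The labels call these 2 arrays biological replicates without naming the plants or sorts. If they carry the same RNA sample, each SD and n of 3 in 16C rests on 2 samples. Some arrays lay as near to another class as to their own. The arrays of 8C replicate 2 and 16C replicate 3 correlated at r = 0.9865, above 0.9823 for the latter with each array of its class. That of 2C replicate 1 correlated at 0.9421 with 4C replicate 1, against 0.941 and 0.9374 within its class.

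**Figure D1:**
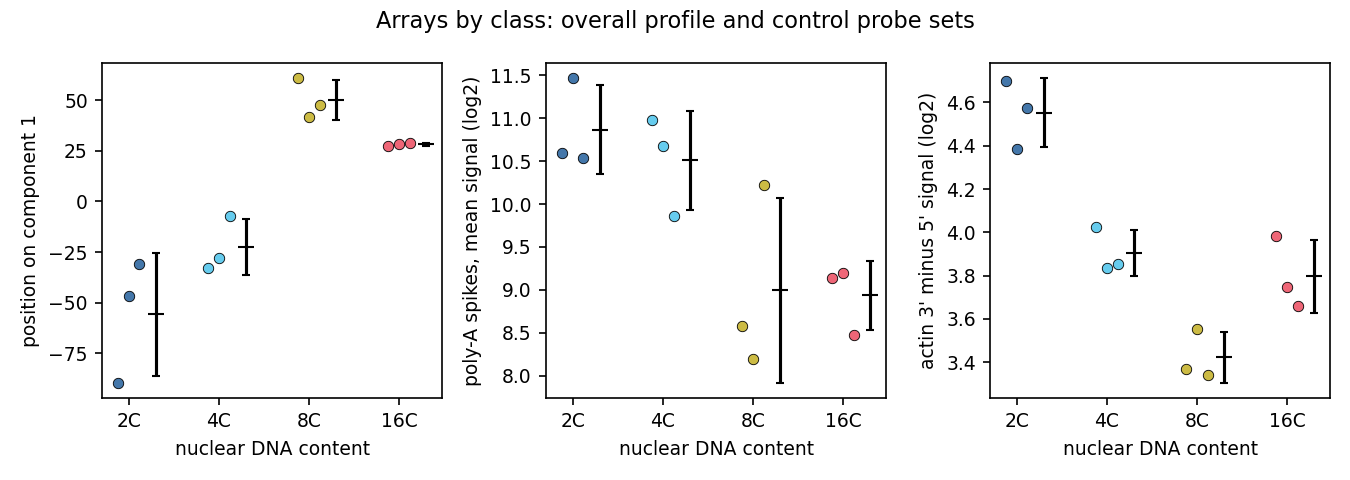
Points are single arrays, 3 per class, and bars are the class mean and SD, with nuclear DNA content on the horizontal axis. The vertical axes give the position on the first principal component, the mean log2 signal of the poly-A spikes, and the log2 signal of actin at the 3' end minus that at the 5' end, whose mean was 4.55 in 2C and 3.42 in 8C.

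Which transcripts differed between any of the classes was asked with a moderated F test in limma. It called 3932 probe sets, or 17.3%. Of these, 1735 were highest in 2C, 403 in 4C, 1259 in 8C and 535 in 16C. A change at every doubling was the lesser part, with 306 rising and 411 falling through all 4 classes. In the linear trend per doubling, 2241 probe sets rose and 2653 fell. Such a slope is fitted over all 4 classes and need not hold at every step. The steepest rise was that of AT1G51270, with a slope of 1.40 ± 0.11 log2 units per doubling (SE, adjusted p = 7.01e-05), from a mean of 6.29 in 2C to 10.3 in 16C. AT1G51820, AT5G49780, AT3G51660, AT5G24080 and AT1G17960 rose with slopes of 1.22, 1.22, 1.21, 1.16 and 1.13. AT2G22760, AT5G47740, AT2G21550 and AT3G09960 followed with slopes of 1.09, 1.08, 1.08 and 1.07, where the 2C arrays of AT2G22760 had an SD of 2.52. The steepest falls were those of AT3G48970 (slope -1.51 ± 0.24, adjusted p = 0.00177) and of LCR69 (slope -1.51 ± 0.14, adjusted p = 0.000117). AT3G53100, AT1G60750, SETH6 and AT5G50010 followed with slopes of -1.34, -1.28, -1.28 and -1.28, and AT1G69080, AT1G63420, AT1G12080 and AT1G67720 with slopes of -1.25, -1.25, -1.21 and -1.2. With the actin difference of each array as a covariate, chosen after seeing the data, the F test called 162 probe sets and the trend 0, with 1543 at an unadjusted p below 0.05. The median size of the 4894 slopes went from 0.291 to 0.220 and their median standard error from 0.062 to 0.177, and 4436 had the same sign as before. With the poly-A spikes as a covariate, also chosen then, the counts were 679 and 725. With them the 4894 slopes had a median size of 0.253 and a median standard error of 0.103, and 4862 had the same sign as before. The trend called 3210 and 2993 probe sets without 16C replicate 1 and 16C replicate 2, and the F test 2581 without 16C replicate 2.

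Of the lists fixed beforehand, core and linker histones were lower along the trend than other genes (camera adjusted p = 6.33e-05), but with adjusted p = 0.341 with an estimated correlation. Of 10 measured genes, 6 fell and 4 did not pass the test, and 7 were lower when adjusted over the list alone. HTB4, an H2B gene, fell along the fitted trend by 0.35 ± 0.06 per doubling (adjusted p = 0.0033), H1.1, a linker histone, by 0.39 ± 0.08 (adjusted p = 0.00569) and HTB5 by 0.29 ± 0.07 (adjusted p = 0.0121). Among neighbouring steps, histones were called only from 4C to 8C, with 3 lower. H1.2, HTB1 and HTB11 had slopes of -0.19, -0.35 and -0.34, which passed under 17, 15 and 9 of 23 alternative settings. Only 2 genes of the DNA replication list were measured, and both fell. MCM7, a subunit of the replicative helicase, fell by 0.96 ± 0.09 per doubling (adjusted p = 0.000122), and ICU2, the catalytic subunit of DNA polymerase alpha, by 0.49 ± 0.09 (adjusted p = 0.00344). Transcripts of the plastid and mitochondrial genomes were the other list called, lower with a median slope of -0.18 over 80 genes (camera adjusted p = 6.33e-05, adjusted p = 0.98 with an estimated correlation). Of these, 4 fell, all coding for subunits of mitochondrial complex I (nad4L, nad5, nad6 and nad9), and 0 did when adjusted over the list alone. Without 2C replicate 1 only 1 list was called. With the actin difference as a covariate this list was instead higher, and the histone list was no longer called (adjusted p = 0.866).

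Other lists moved in single members. Of 4 mitotic genes, AUR1, an Aurora kinase, fell along the fitted trend by 0.40 ± 0.09 per doubling (adjusted p = 0.0147). The fall was not even, since among single steps mitotic genes were called only from 4C to 8C, with 3 lower. In 16C against 2C, 0 of the 4 were called. In the auxin list, 2 of 4 genes passed. GH3.3, an enzyme that conjugates auxin to amino acids, had a slope of 0.59 ± 0.19 (adjusted p = 0.047), which passed under 9 of 23 alternative settings and was 0.0015 with the actin covariate. LBD16, a transcription factor of lateral root initiation, had a slope of -0.56 ± 0.10 (adjusted p = 0.00375). Among 11 expansins and xyloglucan endotransglucosylases, which loosen and remodel the cell wall, XTH19 rose by 0.45 ± 0.12 per doubling (adjusted p = 0.0241) and XTH20 had a slope of -0.15 ± 0.05 (adjusted p = 0.0482), which passed under 7 of 22 settings and not over the list alone. BRX1-1, a ribosome assembly factor, was the only called gene of 5 in its list (slope 0.19 ± 0.04, adjusted p = 0.0142). Of 4 endocycle regulators, 0 passed the test on the trend or between neighbouring classes, and 1 was higher in 16C than in 8C when adjusted over the list alone. SIM, an inhibitor of cyclin-dependent kinases that promotes the endocycle, had a mean signal of 6.50 ± 0.75 (SD, n = 3) in 2C and 6.55 ± 0.04 in 16C, with a slope of 0.03 ± 0.09 (SE).

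The step from 2C to 4C was the first doubling. Of the 2 measured genes of the replication list, 1 was lower in 4C. MCM7 fell from 7.68 ± 0.73 (log2, SD, n = 3) to 5.52 ± 0.13, a change of -2.16 ± 0.28 (SE, limma adjusted p = 0.0129). ICU2 changed by -1.07 ± 0.28, which did not pass (adjusted p = 0.119). POLA3, named among the largest falls, changed by -1.78 ± 0.32 (adjusted p = 0.0435) and passed under 9 of 23 alternative settings. The largest fall was that of LCR69, by 2.51 ± 0.44 (adjusted p = 0.0426), which also passed under 9 of 23. EXLB1, TET5, BGLU44, FMO and PWD changed by -2.0, -1.93, -1.89, -1.68 and -1.60, and AT1G78780 and AT1G19540 by -1.78 and -1.57. The largest rise was that of AT3G07600, by 2.35 ± 0.37 (adjusted p = 0.0297), followed by AT4G35030 and AT3G26470 with 2.08 and 2.04. WRKY6, a transcription factor, rose by 1.95 ± 0.34 (adjusted p = 0.0431) and OASA2 by 1.60 ± 0.25 (adjusted p = 0.0317). AT5G48290, AT4G38550, AT2G18480, AT3G25790 and AT1G44160 rose by 1.87, 1.73, 1.68, 1.62 and 1.56, where the probe set of AT4G38550 is of a kind that can take up related transcripts. Of these rises, AT5G48290 passed under 10, WRKY6 and AT3G25790 under 11, OASA2 under 12 and AT3G07600 and AT2G18480 under 13 of 23 settings.

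Mitotic genes were higher in 4C than in 2C by the camera test of the list (adjusted p = 0.0101), but with adjusted p = 0.25 with an estimated correlation. Of its 4 measured genes, 0 passed over all probe sets and 3 were higher when adjusted over the list alone. AUR2, a mitotic Aurora kinase, had 7.18 ± 0.96 (SD, n = 3) in 2C and 8.99 ± 0.74 in 4C. SCL28 had 6.82 ± 0.64 and 7.71 ± 0.72. Histones were lower as a list with 0 of 10 called (camera adjusted p = 0.0101), and expansins and xyloglucan endotransglucosylases higher with 0 of 11 called (camera adjusted p = 0.04). Both had adjusted p = 0.25 with an estimated correlation. Organelle transcripts had a median change of -0.996 (camera adjusted p = 1.31e-16, adjusted p = 0.269 with an estimated correlation), and 3 of 80 fell, or 6 when adjusted over the list alone. Over all genes, 80 probe sets were higher and 57 lower in 4C. The actin 3' minus 5' difference was lower there, 3.90 against 4.55, and that of GAPDH higher, 5.2 against 4.85. The count of 137 depended on single arrays. It lay between 38 and 76 without 2C replicate 2, 8C replicate 3 or any one of the 4C and 16C arrays, and was 438 without 2C replicate 3. More were lower than higher without 2C replicate 3 (162 higher, 276 lower) and without 2C replicate 2 (36 and 40), whereas scaling to reference genes gave 125 and 28. It was 0 with only the 6 arrays of the 2 classes and 0 with the actin covariate, with 2191 and 1109 probe sets at an unadjusted p below 0.05. With that covariate the median size of the 137 changes was 1.18, against 1.21, and their median standard error 0.404, against 0.180.

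The step from 4C to 8C, which is reached only through the endocycle, held the most calls of the neighbouring steps. Of 33 listed mitotic genes 4 were measured, of which 3 fell and AUR3 did not pass, and 4 were lower when adjusted over the list alone. As a list they were lower by camera (adjusted p = 7.18e-05), but with adjusted p = 0.136 with an estimated correlation. AUR2 fell from 8.99 ± 0.74 (SD, n = 3) to 5.75 ± 0.59, a change of -3.24 ± 0.52 (SE, limma adjusted p = 0.00588). SCL28 changed by -2.12 ± 0.37 (adjusted p = 0.0081) and AUR1 by -1.53 ± 0.30 (adjusted p = 0.013). Histones were lower as a list (camera adjusted p = 3.95e-05, adjusted p = 0.136 with an estimated correlation), with 3 of 10 falling and 7 lower when adjusted over the list alone. HTB4 fell by 1.15 ± 0.20 (adjusted p = 0.00745), H1.1 by 0.90 ± 0.24 (adjusted p = 0.0444) and H1.3 by 2.89 ± 0.79 (adjusted p = 0.0453), with an SD of 1.65 among its 8C arrays. MCM7 fell further, by 1.22 ± 0.28 (adjusted p = 0.0249). Organelle transcripts had a median change of -0.22 with 0 of 80 called (camera adjusted p = 0.0129, adjusted p = 0.997 with an estimated correlation). LHCB4.1, listed as a shoot marker, changed by -1.57 ± 0.42 (adjusted p = 0.0422). Under 23 alternative settings H1.1 and LHCB4.1 passed in 11 and H1.3 in 12, against 21 for AUR2, SCL28 and HTB4.

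The largest falls outside the lists were those of AT3G48970, by 4.14 ± 0.75 (adjusted p = 0.00978), and AT5G22860, by 4.06 ± 0.50 (adjusted p = 0.00177), or 17.6-fold and 16.7-fold. AT1G69080, AT2G36200 (a kinesin-5 gene), VPS2.2, AT1G14480, AT2G16990, AT1G75920 and AT3G62040 changed by -3.61, -3.59, -3.55, -3.51, -3.38, -3.19 and -3.18. GH3.3 rose by 2.32 ± 0.59 (adjusted p = 0.0349). AT5G49780, AT1G51820 and AT1G61550 rose by 2.80 ± 0.46, 2.75 ± 0.41 and 2.57 ± 0.65 (adjusted p = 0.00634, 0.00449 and 0.0346). GH3.3 and AT1G61550 passed under 14 of 23 alternative settings, and AT5G49780 and AT1G51820 under 21. AT1G18030, AT2G29995, AT1G63750, AT3G49210 and AT5G07570 rose by 2.44, 2.19, 2.18, 2.05 and 2.04, and AT1G63880 by 2.1. Over all genes, 1075 probe sets were higher and 1176 lower. Of those with a change of at least 2-fold, 307 were higher and 728 lower. Over all 22746 probe sets, called or not, the 3 arrays of each class lay apart for 7203. For any 1 probe set, 10% of the splits lie apart by chance. Probe sets move together, so a single split can set more than that share apart, and the count was not tested against it.

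The actin difference and the poly-A spikes were both lower in 8C than in 4C, by class means of 3.42 against 3.90 and 9.0 against 10.5. The count was 381 with the spike mean as a covariate and 0 with the actin difference as one, both chosen after seeing the data, with 1744 probe sets at an unadjusted p below 0.05 in the latter. It was 766, 1162, 960 and 1407 without 4C replicate 1, 4C replicate 2, 8C replicate 1 and 8C replicate 3. With arrays shifted to equal means of 8 reference genes, 27.9% of calls were higher, against 47.8%.

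**Figure D2:**
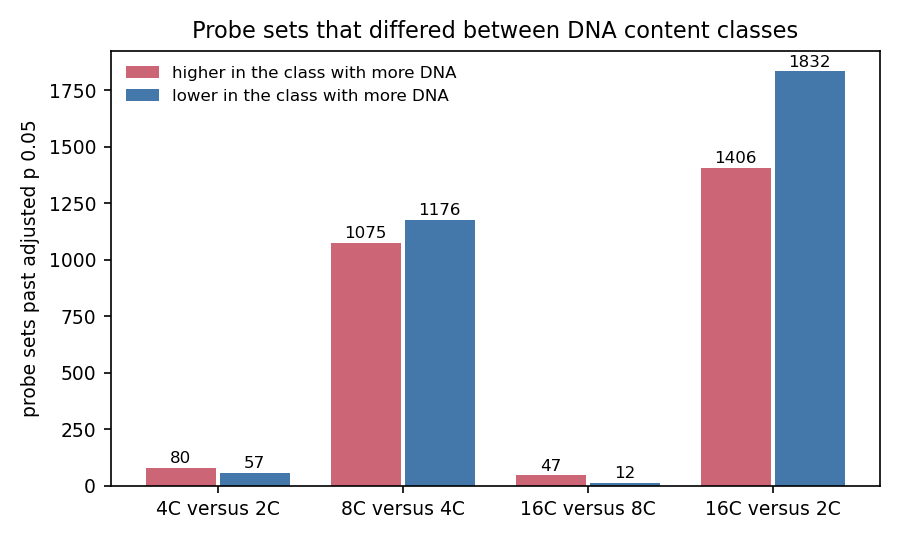
Bars give the number of probe sets past an adjusted p of 0.05 in each comparison of 2 classes, separately for those higher and those lower in the class with more DNA, out of 22746 tested. The step from 4C to 8C had 1075 higher and 1176 lower probe sets, against 80 and 57 from 2C to 4C and 47 and 12 from 8C to 16C.

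From 8C to 16C, the third doubling, the largest changes among the called genes were rises. AT5G24080 rose from 5.36 ± 0.48 (SD, n = 3) to 8.44 ± 0.57, a change of 3.08 ± 0.29 (SE, limma adjusted p = 0.00389), or 8.43-fold. AT1G03660 rose by 2.64 ± 0.16 (adjusted p = 0.000281), AT1G51860 by 2.22 ± 0.33 (adjusted p = 0.03) and AT1G30870, a peroxidase gene, by 1.99 ± 0.21 (adjusted p = 0.00636). GH9C1, an endoglucanase, rose by 1.52 ± 0.24 (adjusted p = 0.0374). AT5G40860, AT3G61300, AT2G28990 and AT2G39690 rose by 1.76, 1.66, 1.60 and 1.54. AT2G16990, which had fallen by 3.38 in the step before, rose by 1.77 ± 0.29 (adjusted p = 0.0412). Both measured genes of the list of epidermis and root hair markers were higher in 16C, whereas of 6 further root hair markers, tested later, 0 passed over all probe sets. EXPA7 rose from 4.41 ± 0.19 to 5.21 ± 0.13, by 0.79 ± 0.12 (adjusted p = 0.03), and EXPA18 from 5.37 ± 0.11 to 6.17 ± 0.12, by 0.80 ± 0.11 (adjusted p = 0.024). All 6 falls named by the rule were smaller than the 10 rises named by it, though larger than the rises of EXPA7 and EXPA18. SAL2, AT5G14690 and CYP71B34 changed by -1.19, -1.03 and -1.01, and AT1G13830, AT1G48670 and AT1G01670 by -0.90, -0.86 and -0.86. Under 24 alternative settings AT1G03660 passed in 24 and AT5G24080 in 23, but GH9C1 in 11, AT2G16990 and AT2G28990 in 12 and AT5G40860 in 13. Of the falls, SAL2 passed in 18 of these, but CYP71B34 in 9 and AT1G13830 in 10. EXPA7 passed in 12 of 23 settings and EXPA18 in 18 of 24.

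Histones and mitotic genes, lower as lists in 8C than in 4C, were higher in 16C than in 8C by camera, with no single gene called. Histones had a median change of 0.43 with 0 of 10 called (camera adjusted p = 4e-04, adjusted p = 0.489 with an estimated correlation). Mitotic genes had a median change of 0.68 with 0 of 4 called and 2 higher when adjusted over the list alone (camera adjusted p = 0.0251, adjusted p = 0.489 with an estimated correlation). Both steps share the 8C arrays. With separate 8C arrays for each step, the medians of both lists were lower and then higher in 6 of 6 splits. This test was chosen after seeing the data. In the latter step the medians ran from 0.369 to 0.425 for histones and from 0.495 to 0.797 for mitotic genes. The splits overlap and reuse the same 4C and 16C arrays, so they show only that no single 8C array made the pattern. Organelle transcripts had a median change of 0.63 with 0 of 80 called (camera adjusted p = 1.15e-12, adjusted p = 0.542 with an estimated correlation), and their median change from 4C to 8C ran from -0.769 to 0.104 over these splits. The actin difference was 3.80 in 16C against 3.42 in 8C, and that of GAPDH 5.58 against 5.05. Over all genes, 47 probe sets were higher and 12 lower, but 64 and 62 without 8C replicate 2, and 421 and 355 with array weights. The count of 59 was 8, 7, 7 and 6 without 8C replicate 1, 8C replicate 3, 16C replicate 1 and 16C replicate 2, 36 without 4C replicate 1, and 110 and 126 without 2C replicate 1 and 8C replicate 2. It was 6 when the pair of closely correlated 16C arrays was averaged as 1, 776 with array weights, and 1 with the actin covariate, where all 59 had the same sign as before, their median size went from 1.29 to 1.09 and their median standard error from 0.166 to 0.245.

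**Figure D3:**
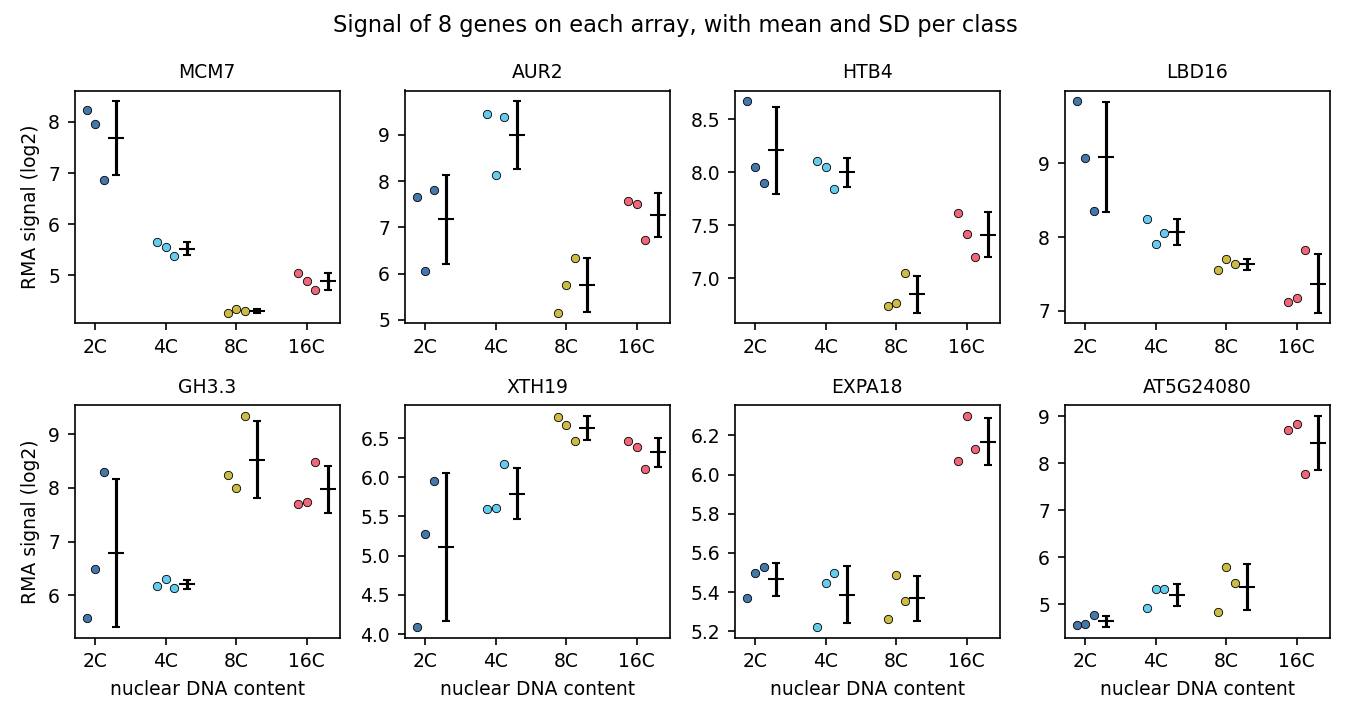
Each panel gives the log2 signal of 1 gene on the vertical axis against nuclear DNA content, with points for single arrays and bars for the mean and SD of the 3 arrays of a class; the vertical axes differ and do not start at 0. MCM7 was highest in 2C (7.68), AUR2 in 4C (8.99), GH3.3 in 8C (8.52), and EXPA18 and AT5G24080 in 16C (6.17 and 8.44).

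Between the extremes, 16C against 2C, AT1G51270 rose by 3.99 ± 0.35 (SE, limma adjusted p = 0.000283), or 15.9-fold, and AT5G24080 by 3.80 ± 0.29 (adjusted p = 0.000177). AT3G51660, AT1G17960, AT5G47740, AT1G51820, AT5G49780, AT1G14120, AT3G09960 and AT4G26470 rose by 3.49, 3.39, 3.15, 3.14, 3.12, 3.06, 3.03 and 2.92. LCR69 fell by 4.26 ± 0.44 (adjusted p = 0.000387), or 19.2-fold. AT1G60750, AT3G48970, AT3G53100, AT1G12320 and SETH6 changed by -3.80, -3.67, -3.64, -3.48 and -3.37, and AT5G50010, AT1G63420, AT1G12080 and AT1G67720 by -3.24, -3.1, -3.08 and -3.05. In all, 1406 probe sets were higher and 1832 lower in 16C. This balance turned with scaling to reference genes, where 51.1% of 2788 calls were higher, against 43.4%. The count of 3238 was 1688 and 1598 without 16C replicate 1 and 16C replicate 2, 507 with the poly-A spikes as a covariate and 0 with the actin difference as one, with 1569 probe sets at an unadjusted p below 0.05. The changes of the 3238 had a median size of 0.838 with the spikes and 0.765 with the actin difference, against 0.940 without, while their median standard error went from 0.195 to 0.290 and 0.494. With the spikes all 3238 had the same sign as before, and with the actin difference 3081 had. With the latter no gene passed, and the changes were 3.31 for AT1G51270 and 4.52 for AT5G24080, but -1.11 for AT3G48970, -1.11 for AT1G12080 and 0.98 for AT5G47740, and nad6 and nad9 changed sign.

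Whether the last doubling acted like the first was tested as the difference between both steps, which share no arrays. It passed for 344 probe sets, of which 176 were positive and the others negative. MCM7, which fell by 2.16 in the first step, changed by 0.58 ± 0.28 in the last (adjusted p = 0.504), and the difference was 2.74 ± 0.40 (adjusted p = 0.0135). WRKY6 changed by 1.95 and -0.89, a difference of -2.84 ± 0.48 (adjusted p = 0.0244). JKD, a zinc finger factor of the ground tissue, changed by 0.42 and -0.64, and its difference was -1.06 ± 0.17 (adjusted p = 0.0194). EXPA7 and EXPA18 had differences of 0.86 and 0.88. Of the 137 and 59 probe sets called in the first and the last step, 10 were called in both, all in opposite directions, where independent lists would share 0.355. These lists are not independent, since both steps use the same spread estimate per probe set, so that number is no sound baseline. Fold changes of both steps correlated at r = -0.244 and rho = -0.137 across probe sets, which are not independent replicates. The count of 344 was 76 and 80 without 16C replicate 1 and 16C replicate 2, 107 and 172 without 8C replicate 1 and 8C replicate 3, 156 and 154 without 4C replicate 2 and 4C replicate 3, and 195 without 16C replicate 3. It was 0 with the actin covariate, with 792 at an unadjusted p below 0.05, and with reference-gene scaling 35.5% of the calls were positive, against 51.2%.

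Markers of the sorted cells and of their neighbours were sparse. Of 4 cortex markers 3 were measured and 0 passed in any step or on the trend, although JKD passed in each neighbouring step when adjusted over the list alone. CO2 itself, whose promoter drove the reporter, had means between 4.02 and 4.25 in the 4 classes. PEP had 4.86 ± 0.86 (SD, n = 3) in 2C and 4.24 ± 0.13 in 16C. The lower quartile of all probe sets lay between 4.15 and 4.30 on the arrays. CO2 in all classes and PEP in 16C were thus near the dim end, where a lack of change says little about the sorted nuclei. SGN3, a receptor kinase of the endodermis and the 1 measured gene of its list, had 4.82 in 2C and 5.68 in 4C (adjusted p = 0.0902). PASPA3, the 1 measured root cap marker, had 5.44 in 4C and 4.53 in 8C (adjusted p = 0.112). RCA, the other measured shoot marker, had 6.74 ± 1.59 in 2C and 6.33 ± 0.10 in 16C. Of 8 measured reference genes and 3 root meristem regulators, 0 passed in any step or on the trend. The lists of DNA repair, wall cellulose, cytokinin, jasmonate and abscisic acid genes had 1 measured gene each (TEB, COB, ARR15, ZAT10 and COR15A), with slopes of 0.01, -0.12, 0.05, 0.17 and 0.07, and 0 of these genes passed. No gene of the lists of DNA methylation, aquaporins, nutrient transporters and stele was named in the probe table, and CCS52A1, SMR1, CYCB1;1, CDKB1;1, KNOLLE, PCNA1, RBCS1A and SCR were not analysed here.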

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

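The tests with the actin difference as a covariate and the range of the 16C means were chosen only after the result was seen. For the tests on left-out 8C arrays and on mixed nuclei, predictions were written before the tests were run. The pattern they address was itself taken from these data. Changes in the first and in the last step differed for some genes. The test of the difference passed for 344 probe sets, and among 100 genes looked at by name it passed for 34. Of these, 31 had been named for a large change in the first or the last step, which largely sets the sign of the difference, so the signs below are no evidence of their own. Genes that rose in the first step had negative differences (log2, last minus first): -3.43 for AT3G07600, -3.21 for AT5G48290, -2.84 for WRKY6, -2.84 for AT4G35030, -2.44 for AT3G26470, -2.38 for AT4G38550, -2.35 for AT2G18480 and -2.05 for AT1G44160. Genes that fell in it had positive ones: 3.06 for LCR69, 2.74 for MCM7, 2.595 for FMO, 2.54 for TET5, 2.12 for EXLB1, 2.11 for BGLU44, 2.01 for AT1G19540, 1.89 for AT1G78780 and 1.72 for PWD. Genes named for their rise in the last step had differences of 3.63 for AT1G03660, 2.90 for AT1G30870, 2.89 for AT1G51860, 2.52 for AT5G24080, 2.44 for AT2G16990, 2.16 for AT3G61300, 1.99 for AT2G28990, 1.51 for AT2G39690, 0.88 for EXPA18 and 0.86 for EXPA7. Those that were lower in it had -2.19 for AT5G14690, -2.14 for AT1G13830, -1.99 for AT1G01670, -1.66 for CYP71B34, -1.61 for SAL2, -1.56 for AT1G48670 and -1.06 for JKD. The standard error was at most 0.62 and the adjusted p at most 0.0424. The count of 344 was 76, 80 and 195 without 16C replicates 1, 2 and 3, 107 and 172 without 8C replicates 1 and 3, 156 and 154 without 4C replicates 2 and 3, and 70 with 16C replicates 1 and 2 averaged. With the actin difference as a covariate limma called 0, with 792 at an unadjusted p below 0.05, as the median standard error of the 344 went from 0.266 to 0.629 and their median size from 1.59 to 1.19, with the same sign for 340. The lost calls are thus no evidence for RNA quality as a source. It is not excluded either, since the actin difference moved in opposite directions in the 2 steps, from 4.55 to 3.90 and from 3.42 to 3.80. The GAPDH difference rose in both steps, from 4.85 to 5.2 and from 5.05 to 5.58, so the 2 measures disagree here. Of 100 splits of the 12 arrays into 4 classes, the real one included, only the real one gave as many calls. The highest of the others gave 81, so arrays placed in classes at random are an unlikely source of this count. These splits mix all 4 classes, so they cannot test the difference between the 2 steps apart from other differences between classes.

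A pattern over the probe sets called from 4C to 8C is a partial return of the 16C arrays toward 4C. It does not account for all genes above. The 16C mean lay outside the range of the 4C and 8C means by more than 2 standard errors for 12 of the 34, of which only 3 were among the 20 not chosen for their change in the last step. It lay far outside for AT1G03660 with 6.25 in 4C, 6.28 in 8C and 8.92 in 16C, and neither a return nor mixed nuclei of 4C can give such a value. On probe sets called with 2 of the 8C arrays, the 8C array that was left out lay 1.41, 0.92 and 1.09 log2 units from the 4C mean, and each time farther than all 3 of the 16C arrays, by at least 0.19. That argues against mere selection of extreme 8C values. For the called probe sets, nuclei of 4C mixed into the 16C gate may be a source: the mixed share worked out from probe sets lower in 8C averaged 0.202, 0.190 and 0.170 on the 3 arrays, and that from probe sets higher in 8C 0.150, 0.159 and 0.169, a mean difference of 0.0282. These averages hide a wide spread, since with single 8C arrays left out the latter share ran from -0.126 to 0.319, and a real partial return in all genes would look alike. A loss of 5' ends stays open, since the median return was 0.325 without and 0.194 with the actin difference as a covariate, a ratio of 0.598, with median standard errors of 0.200 and 0.304. With the poly-A spikes as a covariate, also tried after the result was seen, it was 0.329; a biological difference of the 16C class, which the design names, was not separately tested and stays open too.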

How the results depend on the processing

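The poly-A spike, actin and averaging alternatives were chosen after seeing the data. The actin 3' minus 5' difference as a covariate gave the lowest count in each of the comparisons, the trend and the F test, which for 4C versus 2C fitting only the arrays compared matched. With it limma called 0 probe sets for 4C versus 2C, 8C versus 4C, 16C versus 2C, the trend per doubling and the late minus early step, 1 for 16C versus 8C and 162 in the F test, where 1109, 1744, 1569, 1543 and 792 probe sets had an unadjusted p below 0.05 in the first 5. The classes hold 92.7% of the variance of that difference, so the covariate raised the median standard error of the 8C versus 4C calls from 0.200 to 0.357, while their median size went from 0.954 to 0.755. With the poly-A spikes, 70.1% of whose variance lay between classes, the counts were 381 for 8C versus 4C, 507 for 16C versus 2C, 725 for the trend and 679 in the F test, but 112 for 4C versus 2C, 70 for 16C versus 8C and 401 for the late minus early step, against 137, 59 and 344. With 16C replicates 1 and 2 averaged they were 6 for 16C versus 8C, 1577 for 16C versus 2C, 3064 for the trend, 70 for the late minus early step and 2599 in the F test.

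Without shared and unassigned probe sets, so with fewer tested, the counts were 66, 1136, 28 and 1663 for 4C versus 2C, 8C versus 4C, 16C versus 8C and 16C versus 2C, 2544 for the trend, 159 for the late minus early step and 1999 in the F test. A 2-fold minimum left 91, 1035, 37 and 1491 of those 4 comparisons and, asked of the 2C and 16C means, 1719 of the trend. With only the arrays compared, the counts were 0 for 4C versus 2C (2191 at an unadjusted p below 0.05), 96 for 16C versus 8C and 2059 for 16C versus 2C. Array weights gave 776 for 16C versus 8C and 610 for the late minus early step; the cause was not tested. Leaving out each array in turn gave 38 to 438 for 4C versus 2C, 766 to 3229 for 8C versus 4C, 6 to 126 for 16C versus 8C, 1598 to 3964 for 16C versus 2C, 2993 to 5335 for the trend, 76 to 498 for the late minus early step, 2581 to 4306 in the F test, 1 to 3 for the lists and a p of 0.0131 to 0.13 for GAPDH. Where an arm keeps 2 arrays, these are assumed to vary like the other classes.

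The lists called on the trend were 2, 0 with an estimated correlation, 1 with fry (histones) and 1 with the actin covariate, where organelle transcripts were higher. Scaling to reference genes shifted the median of all probe sets by 0.1475 for 4C versus 2C, to 0.152, and by -0.1457 for the late minus early step, to -0.1681, and moved the share of higher calls from 58.4% to 81.7% for 4C versus 2C, from 47.8% to 27.9% for 8C versus 4C and from 51.2% to 35.5% for the late minus early step. The labels give the replicate numbers no shared origin, and the arrays bore out a pairing only in part: 9 of 18 same-number pairs had deviations correlated above 0.1 (from -0.487 to 0.489), among them all 3 of 4C with 16C (0.162, 0.431 and 0.489), and 6 of 12 arrays correlated best with their own number. With the replicate block the counts were 81 for 4C versus 2C and 27 for 16C versus 8C, and no other count moved by over 1.5 times. Of 3391 values of named genes under alternatives, 2670 stayed past the threshold, 715 did not and 6 changed sign, all with the actin covariate: the slopes of AT2G22760 (-0.0899), HTB11 (0.08), nad6 (0.0974) and nad9 (0.0486), and 16C versus 2C for nad6 (0.1098) and nad9 (0.0402). Signal over background is not known, so values of dim probe sets have no stated limit.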

Other observations

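Gene families that share the letters of a symbol were tested as lists only after the annotation was seen. The covariates and the left-out 4C and 8C arrays on the break between 4C and 8C were chosen after seeing the data. The splits of arrays were not. The root hair list was written down before its own test, but after EXPA7 and EXPA18 had been seen. The genes named from these families were chosen after their values were seen. Of 30 families with at least 8 measured genes, the 10 alpha-expansins had a median change of 0.13 from 8C to 16C (camera adjusted p = 0.0323, adjusted p = 0.461 with an estimated correlation), with only EXPA7 and EXPA18 called and EXPA4, EXPA8 and EXPA9 at -0.05, -0.07 and -0.20. Subtilases, a family of proteases, had a median change of 0.24 in the same step with 0 of 8 called (camera adjusted p = 0.0323, adjusted p = 0.219 with an estimated correlation). In the step from 4C to 8C, SBT4.12 fell by 2.49 ± 0.38 (SE, limma adjusted p = 0.00508) and SBT3.12 fell as well (adjusted p = 0.00229). Ubiquitin-specific proteases had a median change of -0.29 from 8C to 16C with 0 of 12 called (camera adjusted p = 0.0323, adjusted p = 0.219 with an estimated correlation). Genes of the autophagy family ATG had a median change of -0.38 from 2C to 4C with 0 of 8 called (camera adjusted p = 0.00469, adjusted p = 0.441 with an estimated correlation), and ATG8B fell along the trend by 0.44 ± 0.06 per doubling (adjusted p = 0.00113).

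EXPA7 and EXPA18, which are root hair genes, were higher in 16C than in 8C. Root hair nuclei in the 16C sort may be a source, although the sort by the cortex reporter would remove those that lack it. Of 42 root hair markers written down before the test, 6 were measured, and their median change from 8C to 16C was 0.556, against 0.796 for EXPA7 and EXPA18, which had been seen before. Of these, 0 passed over all probe sets and 3 when adjusted over the list alone, namely AT5G04960 (0.995 ± 0.234), AT4G26010 (0.78 ± 0.24) and AT1G34510 (0.55 ± 0.19), while AT4G30320 changed by -0.04 ± 0.14 (SE). Levels in 2C differed: AT4G26010 had 5.82 in 2C and 5.48 in 16C, but AT3G49960 had 5.13 and 5.46, EXPA7 4.47 and 5.21, and EXPA18 5.46 and 6.17. The brightest, AT5G17820, had 8.75 in 2C, 8.26 in 8C and 8.82 in 16C, and was the 1 of the 6 above the median signal of all probe sets. How many of these genes the cortex itself expresses is not known here, so expression there stays open.

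The large break between 4C and 8C came with lower poly-A spikes and a lower actin 3' minus 5' difference. With the spikes as a covariate the fold changes of the 2251 called probe sets had a median of 0.929 of their former size (quartiles 0.760 and 1.09), and 308 stayed called in the same direction, as the median standard error rose from 0.20 to 0.26 and the median size went from 0.95 to 0.85. With the actin difference as a covariate the median ratio was 0.818, and 0 stayed called, as the median size went to 0.76 and the standard error to 0.36. The 16C arrays had actin differences (3.66 to 3.98) that overlapped those of 4C (3.83 to 4.03), and yet lay apart from 4C. With a 4C and an 8C array left out of the calls, they lay from the left-out 4C array at 0.609 to 0.797 of the distance of the left-out 8C array, where the class means of actin predict 0.224 if loss of 5' ends were the whole cause. This points against it as the whole cause but does not exclude it. The 95% interval of the prediction ran from -0.495 to 0.710, and only 5 of 9 choices lay above it. The GAPDH 3' minus 5' difference, the measure planned first, also fell and then rose, but its 16C mean lay above that of 4C. Its means were 5.2 in 4C, 5.05 in 8C and 5.58 in 16C (exact permutation adjusted p = 0.0608), and it was not used as a covariate. RNA input, loss of 5' ends and DNA content cannot be told apart for these calls, because the class means of the spikes were lower in both 8C and 16C, although 8C replicate 3 had 10.22, above 9.86 in 4C replicate 3, and because 3 arrays per class fix the actin difference too loosely; the actin difference could itself differ between classes through the actin genes expressed.

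For the counts of calls, other splits of the same arrays were compared. Of 100 splits of the 12 arrays, only the real one gave as many as 3932 probe sets in the F test, with 1521 at most in the others. Only the real one gave as many as 4894 on the trend, with 3727 at most in the others. Arrays placed in classes at random are thus an unlikely source of both counts. The splits mix all classes and leave out other orders of the true classes. They therefore do not test whether the trend follows the order of DNA content. For the lists, 52 of 100 splits gave 2 or more called lists, with 4 at most, so chance is not excluded there. For 2 classes there are only 10 splits, too few for a share under 0.05. The real split, 1 of 10 with a count as large in each case, gave 137 against 32 at most in the others for 4C versus 2C, 2251 against 0 for 8C versus 4C, 59 against 1 for 16C versus 8C and 3238 against 0 for 16C versus 2C.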
